A study of Mus musculus with 18 samples.

How the data were processed

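RNA of distal colon biopsies from 18 BALB/c mice, 3 in each of 6 groups, had been sequenced as polyadenylated RNA with paired reads. The authors quantified transcripts with kallisto on genome build mm10 after FastQC, per the labels; versions and the annotation release are not stated. The deposited gene table holds expected_counts, kallisto estimates summed per gene symbol and rounded, for 16321 genes whose counts sum to at least 50 over the 18 libraries. A deposited gene table of TPM, a length-scaled share of transcripts, covers the same genes. The deposited transcript tables of each library give the estimated count, the TPM and the effective length of each transcript, per the file headers. Of the transcripts, 97.68% matched the GENCODE annotation of GRCm38, from which positions were taken. Library totals are given with the results; a count of 0 was read as up to 3 counts, and such limits cover counting error only.

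Groups were taken from the labels as genotype and age. Counts were normalised with TMM and tested in edgeR 4.0.16 by the quasi-likelihood F-test, with all 18 libraries in 1 fit of 6 group means; filterByExpr kept 16300 genes. P values are two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.394. Comparisons were Il10KO against wild type at 6 weeks, weeks 8, 10, 12 and 14 against week 6, and consecutive ages from week 8 on, together with a test across all 5 ages and a test of the slope on log10 lipocalin with age as a factor in the 15 Il10KO libraries. CPM are TMM-scaled, with a prior count of 2 on the log2 scale. For genes without a count in 1 group the fold is a lower bound against 3 counts over the group.

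A set of 42 gene lists, written from general knowledge, was tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison) and again with an estimated correlation; lists with fewer than 5 tested genes had no test. Genes called within a list were also counted with p adjusted over the list alone. Lipocalin was compared with age and with Lcn2 by permutation tests with 100000 resamples and an exact permutation test in SciPy 1.17.1. Tests, lists, comparisons, most alternatives and the rule for naming genes were set before the data were examined. The rule takes, among called genes whose groups do not overlap and whose mean log2 CPM is at least 1 in a group, the 6 largest rises and 6 largest falls; for each passing list, the 3 called members with the largest change, or the member with the smallest p if none was called; Il10 and Lcn2 always; and the 5 smallest p of the slope test and the test across ages. Among the largest rises and falls, gene models without a standard symbol and immunoglobulin or T cell receptor variable segments are counted and not named. Not every gene or passing list that the rule covers is given in the text.

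Alternatives were DESeq2 1.42.0, limma-trend on log2 TPM with pseudocounts of 1 and 0.1, RLE or library size in place of TMM, other filters, transcript sums with a length offset, RIN as a covariate, cage as a factor, the replicate number as a block, only the compared groups, wild type as the reference, and leaving out single libraries or those of low RIN. Voom with a weight per group, a fit without the week 14 libraries, and list tests without week 10 replicate 1 or week 14 replicate 1 were chosen after the data were seen. The steps were tested on simulated data with 200 changed genes, where edgeR recovered 45% to 68% of genes changed 4-fold and 1% to 9% of genes changed 2-fold in the comparisons and the test across ages, with 1.61% to 8.7% false calls, and DESeq2 gave 36.8% false calls for week 10 against week 6. A fit of only the compared groups recovered 0% to 14% of genes changed 4-fold and 0% of genes changed 2-fold. The simulation drew every group with the same spread per gene. Real groups differed: the weight per group in voom, higher for less spread, was 3 at Il10KO week 6 and 0.177 at week 14. The recovered and false shares therefore describe equal spread and not these groups. R was 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.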

Results

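Colitis that develops without interleukin 10 was followed in the distal colon of 18 BALB/c mice by sequencing of polyadenylated RNA. Interleukin 10 is a cytokine that restrains macrophages and T cells, and mice that lack its gene (Il10KO) develop spontaneous colitis. The wild type was sampled at week 6 of life and the knockout at weeks 6, 8, 10, 12 and 14, with 3 mice in each of the 6 groups and each mouse sampled at 1 age. Without wild-type mice after week 6, later changes cannot be told apart from those of growth and age alone. The labels also give each mouse's cage, the RNA integrity number (RIN) of its library and, for all 15 Il10KO mice and 1 wild-type mouse, a lipocalin value in ng/g, a marker of gut inflammation. The material in which lipocalin was measured is not stated. Depth, as the total estimated count of each library, was 30016242, 32385719 and 33644962 in the wild type. In Il10KO mice it was 28060701, 28910893 and 27994123 at week 6, 26495521, 30476552 and 27794799 at week 8 and 29747473, 31434575 and 32844928 at week 10. It was 35497101, 27048118 and 29677803 at week 12 and 34306973, 27565728 and 28305260 at week 14. Changes below are log2 fold changes ± SE from 1 edgeR model of all 18 libraries, with n = 3 in each group, tested over 16300 genes with an adjusted threshold of 0.05. The SE was derived from the test, as the change fitted without a prior count divided by the square root of its F statistic. It rests on the spread that the model shares over all groups, and does not measure the spread of the 3 mice in a group. Levels are CPM, counts scaled to effective library size, as mean ± SD over 3 libraries.

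The libraries of week 14 were unlike each other. Replicates 2 and 3 had RINs of 6.5 and 5.8, against 8.4 to 9.3 in the other 16 libraries. In these 2 libraries S100a8 and S100a9, which encode the neutrophil protein calprotectin, took 0.876% and 0.666% of all counts, against 6.1e-05% in week 14 replicate 1. Pearson's r across genes, which are not independent replicates, was 0.796 to 0.961 between week 14 libraries and 0.984 to 0.986 between Il10KO week 6 libraries. Week 14 replicate 1 correlated with each week 6 library at 0.981, just below that range. With the week 6 mean its r was 0.986, where week 6 libraries had 0.988 to 0.990 with the mean of the others. Its closest library was Il10KO week 8 replicate 1, at 0.984. At week 10, replicate 1 had 0.422% of its counts in S100a8 and S100a9, and replicates 2 and 3 had 0.0167% and 0.0020%. The 1st principal component held 63.4% of the variance between libraries.

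The targeted gene was at the limit of detection in every library. Il10 (ENSMUSG00000016529.5, a protein-coding gene on chromosome 1, 131019845 to 131024974, forward strand, GRCm38) is not in the gene table. The transcript tables gave its single transcript 1, 0 and 3 estimated counts in the wild type. All 15 Il10KO libraries had 0. A count of 0 allows up to 3 counts, which is 0.084 to 0.113 CPM by library, so single libraries could not show a difference between the genotypes. The only counts lay in the wild type, but counts pooled over libraries were not tested, and most Il10KO libraries came from older mice. Such limits cover counting error only.

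Lipocalin rose with age. Its mean in Il10KO mice was 3.10 ± 1.40 ng/g at week 6, 114.8 ± 18.1 at week 8, 419.2 ± 117.6 at week 10, 1595 ± 1075 at week 12 and 3364 ± 1173 at week 14 (SD, n = 3). The wild-type value was 0.592 ng/g in 1 mouse. Spearman's rho with age was 0.96 (p = 1e-05 in a two-sided permutation test, the smallest it can give). Week 14 exceeded week 6 by 3361 ng/g (exact permutation test, p = 0.1, the smallest that 3 against 3 can give). Lcn2 (chromosome 2, 32384633 to 32388252) encodes lipocalin 2, which is made by neutrophils and inflamed epithelium. Its transcript did not follow the same course, with 1.04 ± 0.72 CPM at week 6, 2.47 ± 1.5 at week 8, 66.3 ± 42.1 at week 10, 5.78 ± 2.16 at week 12 and 58.3 ± 51.9 at week 14, against 0.904 ± 0.332 in the wild type. Across the 15 Il10KO mice log10 lipocalin and log2 Lcn2 had a Pearson's r of 0.662 (permutation p = 0.00727, adjusted 0.00727 over 4 relations) and a Spearman's rho of 0.725 (p = 0.00299, adjusted 0.00399). After centring both within age, r was 0.586 (p = 0.00183, adjusted 0.00399) and rho 0.729 (p = 0.00258, adjusted 0.00399). Without the 2 mice farthest from the median lipocalin, week 14 replicates 2 and 3, r was 0.552 (permutation p = 0.0489). On the log10 scale the 2 farthest were week 6 replicates 2 and 3, and without them r was 0.49 (permutation p = 0.0852), so that the relation over all ages did not pass without them.

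**Figure D1:**
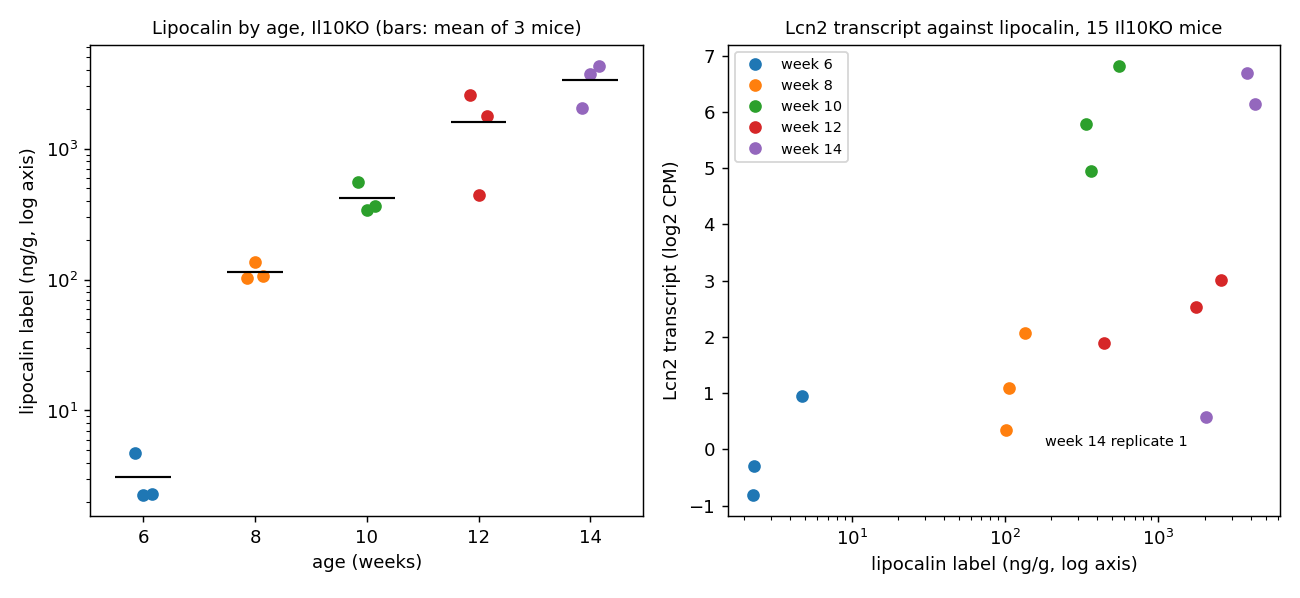
Left, the lipocalin label (ng/g, log axis) against age in weeks for the 15 Il10KO mice, with a bar at each mean of 3 mice, from 3.10 at week 6 to 3364 at week 14. Right, the Lcn2 transcript (log2 CPM) against lipocalin (ng/g, log axis), coloured by age; r was 0.662 over the 15 mice, and week 14 replicate 1 is the point with high lipocalin and a low transcript level.

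At 6 weeks the comparison of Il10KO with wild type asks what differs at the youngest age sampled. No single gene passed. The lists with the clearest shifts held genes of cell division, antibody secretion and antiviral defence. All 22 genes of the proliferation list had positive values in Il10KO, with a median of 0.88, as for Ccna2, a cyclin of S and G2 phase (80.1 ± 19.9 against 36.6 ± 4.7 CPM, 1.13 ± 0.33, adjusted p = 1 with edgeR). None of these genes passed, alone or over the list. The list's adjusted p was 1.08e-21 in camera and 0.0921 with an estimated correlation. Of 13 plasma cell genes, all were positive with a median of 0.95, and 3 passed when adjusted over the list alone. Iglc1, an immunoglobulin light chain gene, had 20.5 ± 12.1 against 3.17 ± 1.87 CPM. The list's adjusted p was 1.98e-12, and 0.312 with an estimated correlation. All 18 type I interferon inducible genes were negative with a median of -1.81 (adjusted p = 1.77e-19, and 0.312 with an estimated correlation). This difference lay largely in 1 library: Rsad2, an antiviral enzyme, had 113 CPM in wild-type replicate 2 against 5.36 and 8.91 in the other wild-type libraries, and its change of -2.51 ± 0.90 became 0.060 without that library. The list then kept an adjusted p of 0.00102. The mast cell list (7 of 8 positive, as Mcpt4 at 1.29 ± 0.52) and the inflammatory monocyte list (10 of 12 positive, as Ly6c2 at 1.72 ± 0.60) had adjusted p = 0.00304 and 0.00755, and 0.586 and 0.988 with an estimated correlation. The handling stress list had a median of -0.31, with Junb, an immediate early gene, at -1.46 ± 0.40 (list adjusted p = 0.00815, and 0.312 with an estimated correlation). Leaving out 1 library ended the handling stress call without wild-type replicate 2 (adjusted p = 0.1), wild-type replicate 3 (0.0983) or Il10KO replicate 2 (0.0768). It ended the mast cell call without Il10KO replicate 1 (0.117) and the monocyte call without wild-type replicate 3 (0.0978). Lcn2 differed by 0.21 ± 0.99. With edgeR 0 genes passed, 394 had an unadjusted p under 0.05 (815 by chance) and the smallest adjusted p was 0.363. The 394 are fewer than chance gives, so the 0 is not read as absence of a difference. The voom weight per group, higher for less spread, was 2.89 for wild type and 3 for Il10KO at week 6, against 0.177 at week 14. A spread shared by all groups may thus not describe these 2. DESeq2 called 25 genes, limma on TPM 0 and edgeR on these 6 libraries alone 65 (3070 of 15376 unadjusted). EdgeR without the 3 week 14 libraries (chosen after the data were seen) called 1 (742 unadjusted). Voom with a weight for each group, chosen after the data were seen, called 354. All wild-type mice shared a cage that held no Il10KO mouse, so cage and genotype cannot be separated.

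Week 8 against week 6 in Il10KO asks which genes change first. The 11 genes that passed all rose. Ido1, which degrades tryptophan, rose by 8.01 ± 1.29, from 0.677 ± 0.213 to 175 ± 207 CPM (adjusted p = 0.0334). Nos2, the inducible nitric oxide synthase, rose by 6.26 ± 0.86 (0.0194), the epithelial gene Clca4b by 7.40 ± 1.11 (0.0254), and Nlrc5, the transactivator of MHC class I, by 3.46 ± 0.58 (0.0397). Btnl2 rose by 5.12 ± 0.80, Steap4, a metalloreductase, by 3.63 ± 0.52, and Pfkfb3, which drives glycolysis, by 1.65 ± 0.27 (0.0334). The spread within week 8 was wide, with Ido1 at 7.68 CPM in replicate 1 and at 111 and 406 in replicates 2 and 3. Of 20 interferon-gamma inducible genes 1 rose, 19 did not pass, and 20 rose when adjusted over the list alone (median 2.89, list adjusted p = 2.25e-31, and 0.12 with an estimated correlation). No MHC class II gene passed, and 7 of 9 did over the list alone, as with Ciita, their master regulator, at 2.36 ± 0.52 (list adjusted p = 2.1e-12, and 0.12 with an estimated correlation). The cytotoxic list had 5 of 12 over the list alone, with Prf1, perforin, at 2.34 ± 0.46 (list adjusted p = 1.14e-10, and 0.12 with an estimated correlation). The T cell list had 1 of 16 over the list alone, Cd8a being at 2.44 ± 0.55 (6.99e-07, and 0.3 with an estimated correlation). In the antimicrobial list 1 of 17 rose (5 rose and 1 fell over the list alone, 4.44e-07, and 0.136 with an estimated correlation). In the hypoxia and glycolysis list 1 of 14 did (4 over the list alone, 3.31e-08, and 0.12 with an estimated correlation). The neutrophil list had 0 of 17 called (2 over the list alone), Cd177 being at 1.86 ± 0.35 (4.42e-05, 0.403 with an estimated correlation and 0.0526 with cage as a factor). Medians were negative for the matrix list (-0.98, Sparc at -1.17 ± 0.33) and the endothelium list (-0.98, Emcn at -0.98 ± 0.35). Their adjusted p in camera were 3.97e-08 and 5.4e-08, and 0.12 and 0.258 with an estimated correlation. With cage as a factor the endothelium list had 0.145. The adipose list, a marker of attached fat, was lower too (median -1.44, 0 of 8 called and 0 over the list alone, 0.00274, and 0.353 with an estimated correlation), so the make-up of the biopsies may have differed. The mitochondrially encoded genes, a sign of RNA quality, moved with them (median -0.58, adjusted p = 9.84e-06, and 0.3 with an estimated correlation). Lcn2 was at 1.24 ± 0.97 (adjusted p = 0.818). The count of 11 fell to 0 without any 1 of the week 6 libraries or week 8 replicate 2, and to 1 without week 8 replicate 3. It was 164 without week 8 replicate 1. DESeq2 called 228 and limma 34. EdgeR without the 3 week 14 libraries (chosen after the data were seen) called 134. EdgeR with cage as a factor called 0 (194 unadjusted), as it did on these 6 libraries alone (2495 unadjusted). In data simulated with equal spread in all groups the fit of 6 libraries recovered 14% of genes changed 4-fold.

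Week 10 against week 6 had 2372 genes higher and 1545 lower, with RINs of 8.5 or more at week 10. Neutrophil genes and the chemokines that attract neutrophils were among the large rises. S100a8 rose by 12.74 ± 2.89 (0.145 ± 0.046 to 1025 ± 1696 CPM, adjusted p = 0.0116), S100a9 by 11.16 ± 2.61, Ltf, lactoferrin, by 8.73 ± 1.39 and Cxcl5, a ligand of the neutrophil receptor CXCR2, by 12.60 ± 2.57 (0.00718). Replicate 1 carried most of this, S100a8 being at 2983, 80.4 and 10.8 CPM in the 3 libraries. Genes without a count at week 6 give lower bounds against a floor of 3 counts over the group. The cornified envelope gene Sprr2h was at least 1430-fold higher, the antimicrobial lectin Reg3b at least 1130-fold, Gml at least 350-fold, and the chemokine Cxcl3 at least 347-fold. Of 17 neutrophil genes 14 rose and 3 did not pass (15 adjusted over the list alone, list adjusted p = 1.72e-06, and 0.409 with an estimated correlation). In the chemokine list 11 of 16 rose (13 over the list alone, 3.39e-06, and 0.409 with an estimated correlation). All 20 interferon-gamma inducible genes rose, as did Ido1 by 9.06 ± 1.34, the immunity-related GTPase Iigp1 by 7.04 ± 1.05 and the T cell chemokine Cxcl11 by 7.91 ± 1.77 (20 over the list alone, 2.26e-18, and 0.409 with an estimated correlation). Ido1 was even across the replicates, at 363 ± 22 CPM. Of the type I interferon inducible genes 11 of 18 rose, as Zbp1, a sensor of nucleic acids, by 4.42 ± 0.92 (14 over the list alone, 1.16e-06, and 0.444 with an estimated correlation). Against the wild type this list had adjusted p = 0.0553. Cytotoxic genes rose in 10 of 12, among them the granzymes Gzma by 7.83 ± 1.41 and Gzmb by 6.27 ± 1.35 (10 over the list alone, 5.88e-06, and 0.409 with an estimated correlation). MHC class II genes rose in 7 of 9, as H2-DMb1 by 3.48 ± 0.69 and Ciita by 2.58 ± 0.52 (7 over the list alone, 8.61e-06, and 0.409 with an estimated correlation). T cell genes rose in 5 of 16, as Cd8a by 2.87 ± 0.56 (5 over the list alone, 0.00276, and 0.495 with an estimated correlation). Th1 genes rose in 6 of 12, as Il12b, a subunit of interleukins 12 and 23, by 3.58 ± 0.82 (7 over the list alone, 0.000889, and 0.409 with an estimated correlation). Of the inflammatory cytokines 7 of 12 rose, with Tnf by 6.17 ± 1.00, Il1b by 5.98 ± 1.43 and Il6 by 5.22 ± 1.81 (7 over the list alone, 0.0036, and 0.495 with an estimated correlation).

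Epithelial and stromal genes moved both ways at week 10. Of 17 antimicrobial genes 11 rose, 2 fell and 4 did not pass (12 and 2 over the list alone), with Nos2 up by 9.00 ± 0.97 (1.03 ± 0.40 to 529 ± 144 CPM, adjusted p = 0.000361), Reg3g by 8.15 ± 2.02 and Lcn2 by 5.98 ± 1.12 (0.00493). The list's adjusted p was 2.58e-05, and 0.409 with an estimated correlation. Pfkfb3 rose by 3.22 ± 0.28, the smallest p of the comparison (6.7e-09, adjusted 0.000109). Hk2, hexokinase 2, rose by 2.94 ± 0.33, among 8 of 14 hypoxia and glycolysis genes (10 over the list alone, 7.3e-07, and 0.409 with an estimated correlation). In the IL-10 receptor signalling list 4 of 10 rose, as Socs3, an inhibitor of cytokine signalling, by 4.91 ± 0.83 and Bcl3 by 2.06 ± 0.26 (5 over the list alone, 0.000598, and 0.088 with an estimated correlation). The mice of both ages lacked Il10, so these rises are not read as a response to interleukin 10. Socs3 and Bcl3 also answer to other cytokines. Of 13 regenerative epithelium genes 5 rose, as Ly6a, the stem cell antigen Sca-1, by 5.65 ± 0.96 and Sprr1a by 6.10 ± 1.26 (6 over the list alone, 0.0383, 0.498 with an estimated correlation and 0.0699 with cage as a factor). Large falls were seen in Cyp2c55, a cytochrome P450 of the colon (-9.17 ± 2.10, 245 ± 69 to 0.420 ± 0.523 CPM, adjusted p = 0.0121), Slc30a10, a manganese exporter (-5.94 ± 2.03), Galnt17 (-5.45 ± 1.09), Cyp2c69 (-5.42 ± 0.86), Klb, the co-receptor beta-klotho (-5.37 ± 1.2), and Hsd3b3 (-5.29 ± 1.04). In the xenobiotic list 10 of 18 fell and Ces2e, a carboxylesterase, rose by 1.73 ± 0.33 (12 fell over the list alone, 0.00011, and 0.409 with an estimated correlation). Of 24 colonocyte genes 7 fell, as Car1, carbonic anhydrase 1, by 3.61 ± 0.51 and the drug exporter Abcb1a by 4.42 ± 1.09, and 3 rose, as the water channel Aqp4 by 2.79 ± 0.32 (3 and 8 over the list alone, 0.0155, and 0.458 with an estimated correlation). Endothelial genes fell in 5 of 11, as the angiopoietin receptor Tek by 2.17 ± 0.55 (11 over the list alone, 0.000137, and 0.444 with an estimated correlation). Enteric neuron and glia genes fell in 8 of 15, as the glial factor Sox10 by 2.56 ± 0.83 and neuronal Nos1 by 2.41 ± 0.80 (11 over the list alone, 3.67e-05, and 0.409 with an estimated correlation). Matrix genes fell in 8 of 21, as the collagen Col6a3 by 2.33 ± 0.58, and rose in 2 (12 and 3 over the list alone, 0.0107, and 0.458 with an estimated correlation). The smooth muscle list had a median of -1.17 with 0 of 13 called (0.00276, and 0.495 with an estimated correlation). The adipose list, a marker of attached fat, had a median of -3.00 with 2 of 8 lower (5 over the list alone, 0.0155, and 0.458 with an estimated correlation), so the make-up of the biopsies may have differed too. Without week 10 replicate 1 the calls ended for the inflammatory cytokine (adjusted p = 0.0563), colonocyte (0.0895), regenerative epithelium (0.183) and smooth muscle lists (0.0661). The gene count was 767, 994 and 1103 without each week 6 library, 1090 and 1824 without week 10 replicates 1 and 2, and 5242 without replicate 3. It was 2 with cage as a factor and 6177 on these 6 libraries alone. On the TPM scale, where the median of all genes fell by 0.34, limma called 978 higher and 2272 lower. EdgeR without the week 14 libraries called 8354.

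**Figure D2:**
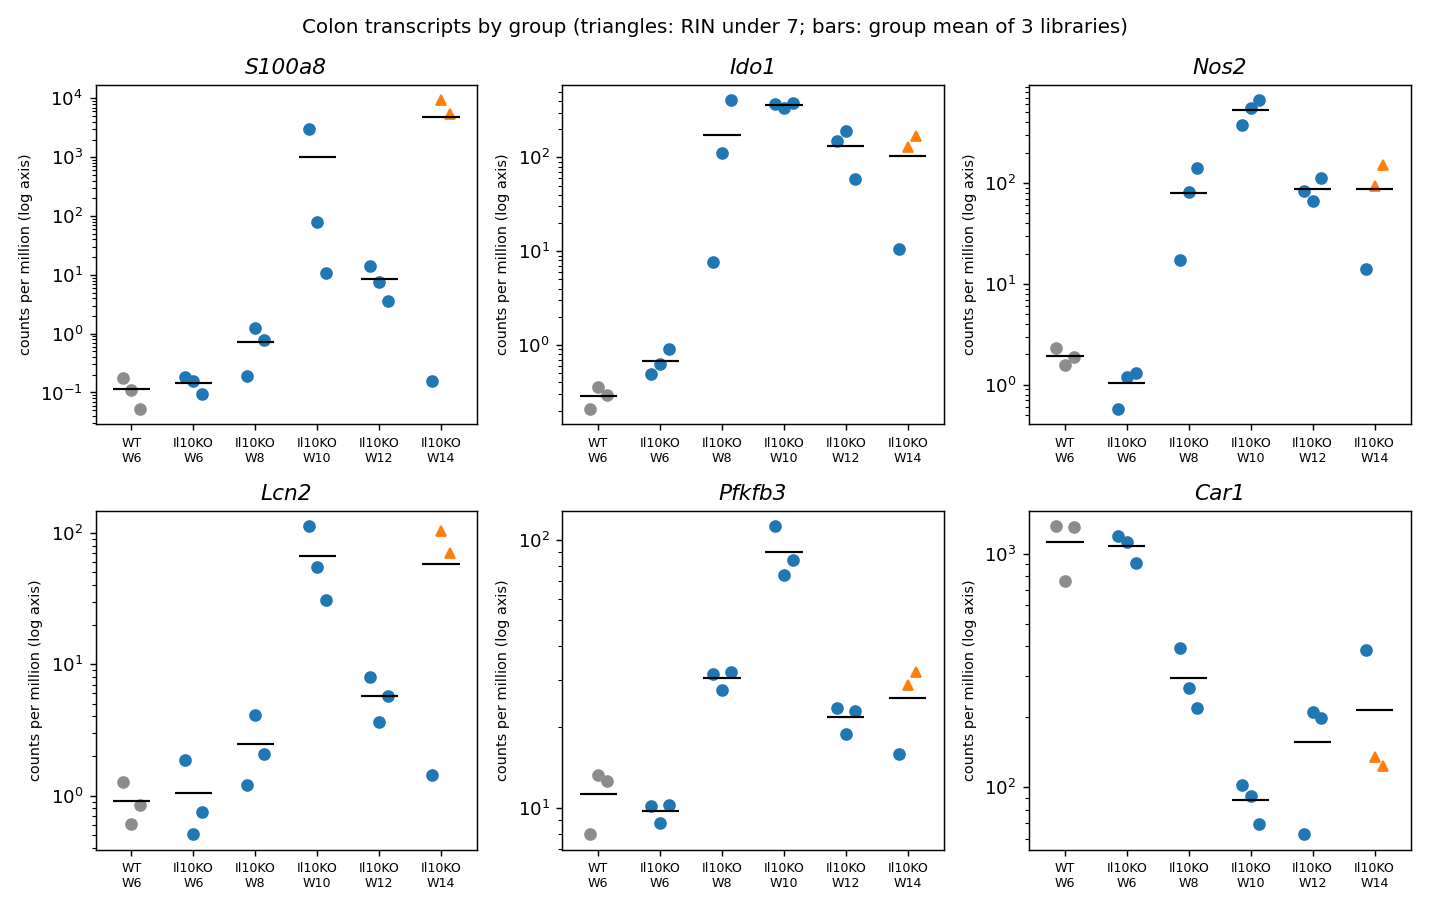
CPM (log axis) of 6 genes in the 18 libraries by group, with 1 point per library and a bar at the mean of 3; triangles mark the 2 libraries with a RIN under 7. S100a8 ranges from 10.8 to 2983 within week 10, Pfkfb3 and Nos2 have their highest mean at week 10, and week 14 replicate 1, the circle, lies apart from the triangles.

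Week 12 against week 6 asks how expression stood later, with all RINs at 8.6 or more. In this model 221 genes were higher and 80 lower, and cytotoxic, interferon-gamma and MHC class II genes were among those that rose. Gzma rose by 7.12 ± 1.38 (0.228 ± 0.064 to 32.3 ± 8.0 CPM, adjusted p = 0.0309), Gzmb by 5.72 ± 1.32, Ido1 by 7.61 ± 1.27 (0.0209), Clca4b by 7.05 ± 1.09, Nos2 by 6.39 ± 0.87 (0.011), the epithelial surface gene Plet1 by 6.56 ± 1.40 and the GTPase Tgtp1 by 6.30 ± 1.22. Of 20 interferon-gamma inducible genes 9 rose (20 over the list alone, list adjusted p = 5.19e-14, and 0.422 with an estimated correlation). MHC class II genes rose in 7 of 9, as H2-Ab1 by 2.85 ± 0.56 and H2-DMb1 by 3.13 ± 0.68 (9 over the list alone, 2.54e-08, and 0.422 with an estimated correlation). Cytotoxic genes rose in 4 of 12 (10 over the list alone, 7.9e-07, and 0.422 with an estimated correlation). Chemokines rose in 3 of 16, as Ccl8 by 5.63 ± 1.19 (10 over the list alone, 2.27e-07, and 0.422 with an estimated correlation). The T cell list had 1 of 16, Cd8a, up by 2.89 ± 0.56 (12 over the list alone, 1.04e-05, and 0.56 with an estimated correlation). In the antimicrobial list 3 of 17 rose, as the phospholipase Pla2g2a by 5.46 ± 1.13 (10 over the list alone, 3.25e-05, and 0.422 with an estimated correlation). The neutrophil list had 1 of 17, Ltf, up by 5.59 ± 1.24 (2 over the list alone, 0.000263, and 0.667 with an estimated correlation). The plasma cell list had 1 of 13, Ighg3, up by 4.19 ± 0.90 (4 over the list alone, 0.0038, and 0.667 with an estimated correlation). Large falls were seen in Galnt17 (-4.21 ± 1.01), Ndnf (-2.86 ± 0.67), Car1 (-2.78 ± 0.50, adjusted p = 0.0254), the imprinted gene Peg10 (-2.73 ± 0.66) and Syt4 (-2.48 ± 0.43). Matrix genes fell in 7 of 21, as the collagens Col1a2 by 2.39 ± 0.56 and Col4a1 by 2.44 ± 0.59 and the tenascin Tnc by 2.29 ± 0.54 (13 over the list alone, 3.11e-07, and 0.422 with an estimated correlation). The proteoglycan gene Vcan, which is in the inflammatory monocyte list and not the matrix list, fell by 1.85 ± 0.38. It ran against its own list, which had a median of 1.40. In the enteric neuron list Ret, a receptor of enteric neurons, fell by 1.72 ± 0.39, 1 of 15 (11 over the list alone, 3.65e-06, and 0.422 with an estimated correlation). No endothelial gene passed and 11 of 11 did over the list alone, Vwf being at -2.36 ± 0.64 (7.9e-07, and 0.422 with an estimated correlation). The smooth muscle list had 0 of 13 called and a median of -0.94 (0.00757, and 0.667 with an estimated correlation). Lcn2 was at 2.47 ± 0.98 (adjusted p = 0.12). The count of 301 was 1, 0 and 0 without week 6 replicates 1, 2 and 3, and 13, 9 and 52 without week 12 replicates 1, 2 and 3. With cage as a factor it was 0 (1762 unadjusted). It was 2507 with DESeq2, 9186 with edgeR on these 6 libraries alone and 6688 without the week 14 libraries. Whether more genes changed by week 10 or by week 12 thus depended on the model. Library size alone gave 180 higher and 19 lower, and limma on TPM 187 higher and 477 lower.

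Week 14 against week 6 had 3993 genes higher and 1395 lower, and the count depended on which of the 3 week 14 libraries were kept. Without these 2 libraries edgeR called 0 genes (239 unadjusted), but week 14 is then replicate 1 alone, assumed to vary like the other groups. EdgeR also called 0 with RIN as a covariate (429), with cage as a factor (2517) and on these 6 libraries alone (4257). RIN differed widely only within week 14 (9, 6.5 and 5.8 in replicates 1 to 3). The fit with RIN thus leans on replicate 1 too and is not a separate check. In data simulated with equal spread in all groups the fit of 6 libraries recovered 0% of genes changed 4-fold. DESeq2 called 7645, and edgeR without replicate 1 called 11335. Antimicrobial, neutrophil and chemokine genes were again among the large rises. Reg3b was at least 21100-fold higher, Sprr2h at least 1970-fold, Sprr2k at least 1260-fold, Cxcl3 at least 1240-fold and Spink6, a protease inhibitor, at least 906-fold, each without a count at week 6. S100a8 rose by 15 ± 3.07, at 0.158, 9273 and 5436 CPM in replicates 1 to 3 (adjusted p = 0.00617), S100a9 by 13.54 ± 2.80, Cxcl5 by 13.44 ± 2.62, Reg3g by 11.55 ± 2.25 and Lcn2 by 5.80 ± 1.11 (0.00617). Of 17 neutrophil genes 15 rose (15 over the list alone, list adjusted p = 2e-05, and 0.686 with an estimated correlation; 0.0853 without the low RIN libraries). In the chemokine list 13 of 16 rose (14 over the list alone, 4.92e-06, and 0.686 with an estimated correlation). In the antimicrobial list 12 of 17 rose (12 over the list alone, 5.63e-05, and 0.686 with an estimated correlation). Inflammatory cytokines rose in 10 of 12, as Il1b by 6.92 ± 1.49 and Tnf by 6.09 ± 1.00 (11 over the list alone, 0.00101, and 0.686 with an estimated correlation; 0.249 without the low RIN libraries). The interferon-gamma list had 13 of 20, as Cxcl9 by 5.48 ± 1.16 (16 over the list alone, 4.92e-06, and 0.686 with an estimated correlation). The cytotoxic list had 10 of 12, as Gzma by 8.95 ± 1.46 (10 over the list alone, 6.99e-05, and 0.686 with an estimated correlation). The MHC class II list had 6 of 9, as H2-Aa by 2.37 ± 0.56 (6 over the list alone, 0.00228, and 0.686 with an estimated correlation). The T cell list had 8 of 16, as Cd3d by 4.29 ± 0.96 (8 over the list alone, 0.00428, and 0.686 with an estimated correlation). Plasma cell genes rose in 6 of 13, as the antibody gene Ighg1 by 3.94 ± 1.01 and Mzb1 by 3.79 ± 0.93 (9 over the list alone, 0.00269, and 0.686 with an estimated correlation). Mast cell genes rose in 5 of 8, as the protease Mcpt2 by 4.37 ± 1.02 and Hdc, which makes histamine, by 4.25 ± 0.96 (6 over the list alone, 0.0112, and 0.686 with an estimated correlation; 0.0694 without replicate 1). Large falls were seen in Klb (-2.84 ± 1.04), Fndc5 (-2.80 ± 0.55), Kif26b (-2.79 ± 0.71), Galnt17 (-2.77 ± 0.94), the bicarbonate transporter Slc4a4 (-2.72 ± 0.79) and Bmp3 (-2.71 ± 0.85). Car1 fell by 2.32 ± 0.49 among 5 of 24 colonocyte genes that fell and 3 that rose (3 and 5 over the list alone, 0.0438, and 0.686 with an estimated correlation; 0.153 without the low RIN libraries). Endothelial genes fell in 5 of 11, as Tek by 1.72 ± 0.54 (9 over the list alone, 0.00128, and 0.686 with an estimated correlation). The smooth muscle list had 0 of 13 called (0.0435, and 0.78 with an estimated correlation; 0.0623 without replicate 1 and 0.781 without the low RIN libraries). Of 14 lists described for this comparison 9 kept their call in camera without the low RIN libraries, among them the interferon-gamma, cytotoxic and antimicrobial lists. The count of 5388 was 2734, 2781 and 2601 without each week 6 library, and 1880 and 2251 without week 14 replicates 2 and 3. On the TPM scale, where the median of all genes fell by 0.74, limma called 879 higher and 8899 lower.

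**Figure D3:**
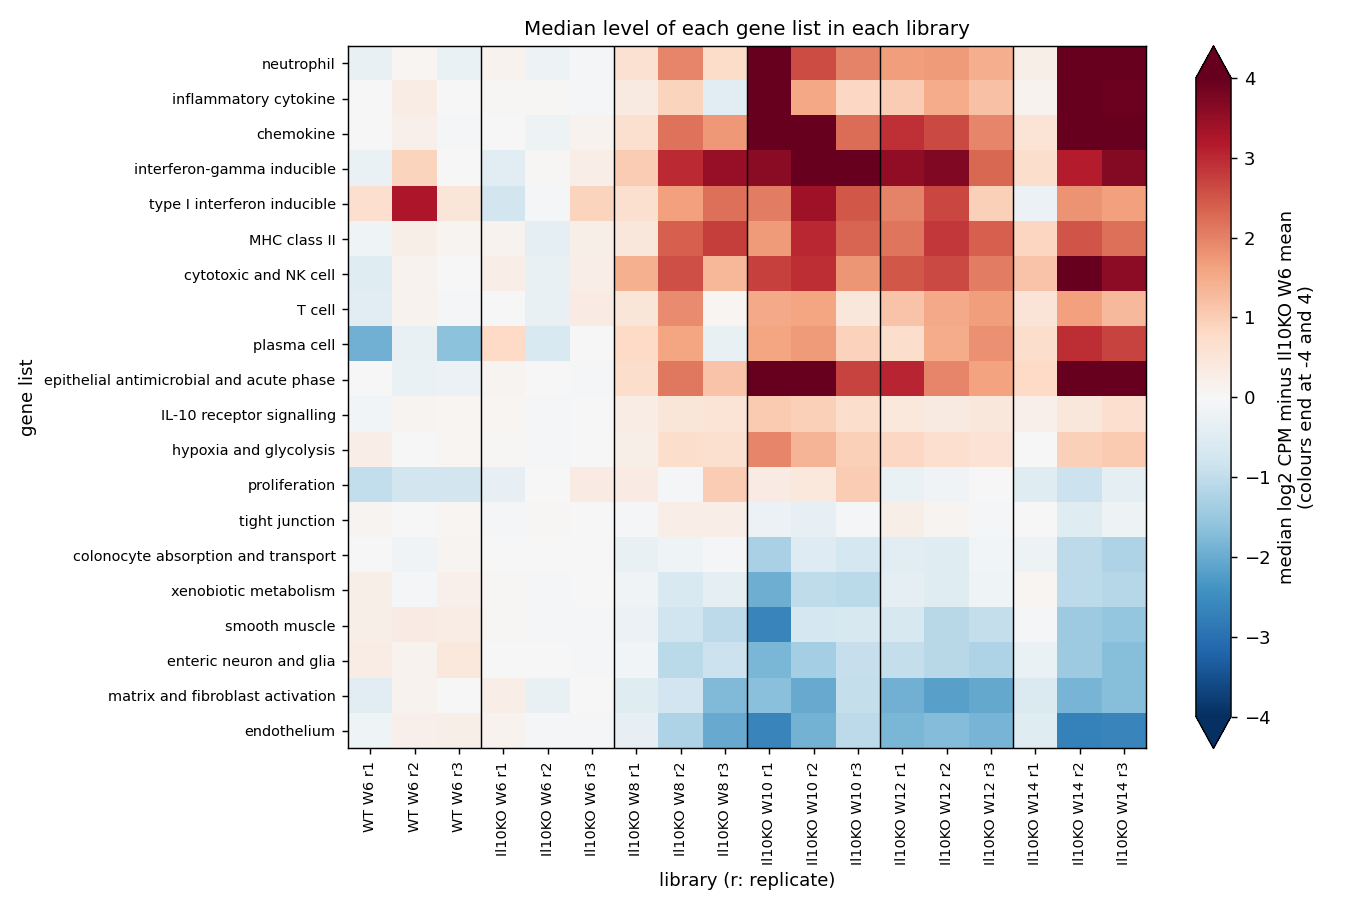
Median log2 CPM of 20 gene lists in the 18 libraries, relative to the mean of the Il10KO week 6 libraries; red is higher, blue is lower, and colours end at -4 and 4. The endothelium list lies between -1.86 and -1.75 in the 3 week 12 libraries. In the neutrophil list week 14 replicate 1 lies nearer the week 6 level than replicates 2 and 3, which show the strongest signal. With replicate 1 as the only week 14 library, the interferon-gamma, cytotoxic and antimicrobial lists still lay above week 6 in camera.

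Consecutive ages ask in which interval genes move. From week 8 to week 10, 19 genes rose and 13 fell. The acute phase gene Lbp, which binds lipopolysaccharide, rose by 2.89 ± 0.55 (15.5 ± 3.2 to 115 ± 34 CPM, adjusted p = 0.048), Tifa, an adaptor in the sensing of bacterial sugars, by 2.80 ± 0.49, Tgm2, a transglutaminase, by 2.27 ± 0.36, Fut2, which fucosylates the epithelial surface, by 2.18 ± 0.29 (0.0178), and Trmt61a, a tRNA methyltransferase, by 1.89 ± 0.27. Lars2 rose by 2.88 ± 0.52, which is uncertain, since this gene holds a stretch alike to mitochondrial ribosomal RNA. The mitochondrially encoded list moved the same way (median 0.55, adjusted p = 0.00327, and 0.552 with an estimated correlation). Sele, E-selectin, which slows leukocytes on the endothelium, rose by 3.82 ± 0.75, Pfkfb3 by 1.57 ± 0.27 and Bcl3 by 1.42 ± 0.25. Falls were seen in Ppfia3 (-2.81 ± 0.40), Edn2, an endothelin (-2.66 ± 0.45), Kazald1 (-2.31 ± 0.38), the ceramidase Acer1 (-2.18 ± 0.38), A4gnt, a glycosyltransferase of gastric-type mucus (-2.08 ± 0.32), and Pdcd4 (-1.81 ± 0.33). S100a8 (10.43 ± 2.60, adjusted p = 0.0891) and Lcn2 (4.74 ± 1.05, 0.0669) did not pass. Of 17 neutrophil genes 0 passed and 12 rose over the list alone (list adjusted p = 2.82e-06, and 0.533 with an estimated correlation). Chemokines had 0 of 16 and 6 over the list alone (0.00024, and 0.533 with an estimated correlation), and interferon-gamma genes 0 of 20, all positive (1.36e-07, and 0.533 with an estimated correlation). One hypoxia gene of 14 rose and 5 did over the list alone (0.000513, and 0.533 with an estimated correlation). So did 1 of 10 IL-10 receptor signalling genes and 4 over the list alone (0.00588, and 0.301 with an estimated correlation). The xenobiotic list had a median of -0.85, 0 of 18 called and 6 lower over the list alone (0.000814, and 0.533 with an estimated correlation). The posterior Hox list, a marker of position along the gut, had a median of -0.34, 0 of 8 called and 2 lower over the list alone (0.0313, and 0.533 with an estimated correlation; 0.0544 without week 10 replicate 1 and 0.178 with cage as a factor). The count of 32 was 0 without week 10 replicate 1 or 3 or week 8 replicate 2 or 3, 1 without week 8 replicate 1 and 0 with cage as a factor (2199 unadjusted). DESeq2 called 881, limma 20, and library size alone gave 12 higher and 4 lower.

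From week 10 to week 12, 34 genes rose and 39 fell, and several genes that had risen by week 10 were lower again. Pfkfb3 fell by 2.05 ± 0.27 (90.2 ± 19.9 to 21.8 ± 2.5 CPM, adjusted p = 0.011), Fut2 by 2.17 ± 0.29 (0.011), Tgm2 by 2.48 ± 0.36, Erich3 by 3.66 ± 0.70, Sting1, an adaptor of DNA sensing, by 1.99 ± 0.31, and Sema6b by 1.98 ± 0.38. Rises were seen in Cyp2c69 (5.24 ± 0.86), Edn2 (3.20 ± 0.46), Ppfia3 (2.85 ± 0.40), Edn1, another endothelin (2.82 ± 0.57), Kazald1 (2.64 ± 0.39) and Ly6g6d (2.57 ± 0.46). Of 14 hypoxia and glycolysis genes 3 fell, Pfkfb3, Hk2 by 1.94 ± 0.32 and Hif1a, the oxygen-sensitive factor, by 1.64 ± 0.32 (7 over the list alone, list adjusted p = 7.66e-09, and 0.192 with an estimated correlation). In the IL-10 receptor signalling list 2 of 10 fell, Bcl3 by 1.44 ± 0.25 and Sbno2 by 1.07 ± 0.22 (4 over the list alone). Its adjusted p was 0.000171, and 0.0382 with an estimated correlation, the only list of any comparison that passed both ways. The mice of both ages lacked Il10, so the list is not read as a response to interleukin 10. The neutrophil list had a median of -3.07, 0 of 17 called and 12 lower over the list alone (8.61e-06, and 0.591 with an estimated correlation). All 20 interferon-gamma inducible genes were negative with 0 called and 1 over the list alone (3.18e-08, and 0.591 with an estimated correlation), as were all 22 proliferation genes, median -0.81 (5.59e-08, and 0.327 with an estimated correlation). The xenobiotic list had a median of 0.79 with 1 of 18 called, Gstm3, a glutathione transferase, up by 1.74 ± 0.35 (3 over the list alone, 1.98e-06, and 0.326 with an estimated correlation). All 12 B cell genes were positive, 0 called (0.00528, and 0.683 with an estimated correlation). Markers of the biopsy itself moved too. The adipose list, of attached fat, had a median of 1.57, with 0 of 8 called and 0 over the list alone (0.0235, and 0.632 with an estimated correlation; 0.054 without week 10 replicate 1). The posterior Hox list had a median of 0.43, with 0 of 8 called and 3 higher over the list alone (0.00208, and 0.326 with an estimated correlation). Lcn2 was at -3.52 ± 0.98 (adjusted p = 0.116). The count of 73 was 30 without week 10 replicate 1, 9 without week 12 replicate 1, 0 without week 10 replicate 3 or week 12 replicate 2 or 3, and 0 with cage as a factor (1194 unadjusted). DESeq2 called 820; limma on TPM gave 7 higher and 48 lower, and library size alone 6 higher and 14 lower.

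From week 12 to week 14 a single gene passed, the unnamed model 2610005L07Rik, which fell by 1.37 ± 0.19 (20.9 ± 1.5 to 8.08 ± 1.26 CPM, adjusted p = 0.0472); it was named after its values were seen. S100a8 was at 9.17 ± 2.45, Lcn2 at 3.33 ± 0.98 and the crosslinking enzyme gene Lox at 1.82 ± 0.45, each with an adjusted p of 0.242. The neutrophil list had a median of 3.65, 0 of 17 called and 12 higher over the list alone (list adjusted p = 3.88e-05, and 0.809 with an estimated correlation), but it lay lower at week 14 with RIN as a covariate (0.0031) and without the 2 libraries of low RIN (0.000709). In the latter fit week 14 is replicate 1 alone, assumed to vary like the other groups. RIN differed widely only within week 14, so the fit with RIN leans on replicate 1 too. All 21 matrix genes were positive (0 called, 3 over the list alone, 0.000285, and 0.809 with an estimated correlation; 0.226 without week 14 replicate 1). Of 12 B cell genes 11 were negative (0.00108, and 0.958 with an estimated correlation; 0.336 without replicate 1). With edgeR 2825 genes had an unadjusted p under 0.05. The count of 1 became 0 without any library of week 12 or without week 14 replicate 2 or 3, and 7707 without week 14 replicate 1, and DESeq2 called 310.

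A test across all 5 ages of Il10KO asks which genes differ between any of them, and 4471 passed (7606 at an unadjusted p under 0.05). The smallest p values belonged to Pfkfb3 (adjusted p = 0.000747), Fut2 (0.00106), Card14, a scaffold of NF-kB signalling (0.00415), Nos2 (0.00415) and Hk2 (0.00415), and each had its highest mean at week 10. Fut2 had mean CPM of 79.5, 141.6, 640.9, 142.6 and 225.0 at weeks 6, 8, 10, 12 and 14, and Card14 14.1, 23.8, 51.7, 22.6 and 21.6. The count was 1412, 1611 and 1564 without week 6 replicates 1, 2 and 3, 1261 and 1770 without week 14 replicates 2 and 3, 11683 without week 14 replicate 1. With cage as a factor it was 0 (1971 unadjusted). For the slope on lipocalin within age 0 of 16182 genes passed with edgeR, and 0 with DESeq2. In edgeR 117 genes had an unadjusted p under 0.05 (809 by chance). The smallest adjusted p, 0.146, was shared by Spink6 and Sprr2f, followed by Gm8556, Sprr2d and Gm6158 at 0.889. Without week 12 replicate 2 the count was 2, and without week 14 replicate 2 it was 1. On data simulated with equal spread in all groups this slope test recovered 0% of genes changed 4-fold, so its count of 0 says little. Estimates for close paralogs (the Sprr2 and Reg3 families, Cyp2c55 and Cyp2c69, granzymes, Tgtp1, Iigp1, immunoglobulin genes) depend on how reads that match several members were shared out, and are uncertain for single members.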

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

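The tests of RNA degradation, a swap, leukocyte RNA, the muscle wall and single wild-type libraries were chosen only after the result was seen.

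Changes from week 6 differed between consecutive ages when the difference was tested directly, in 32 genes between weeks 8 and 10, in 73 between weeks 10 and 12 and in 1 between weeks 12 and 14. The counts are those of the consecutive ages given above and no further test. Without single libraries these counts ranged from 0 to 24, 0 to 70 and 0 to 7707. Other splits of the 6 libraries gave at most 0 genes for the first and second, where the 10 splits are too few for a share under 0.05. Between weeks 12 and 14, 4 of 10 splits gave as many, and 1 that grouped week 14 replicate 1 with week 12 replicates 1 and 3 gave 5329 genes, which points to a structure of the samples.

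For the other comparisons of 3 against 3 libraries the 10 splits are also too few for a share under 0.05. All 10 splits gave the 0 genes of the genotype comparison. For weeks 8, 10 and 12 against week 6 the real counts were 11, 3917 and 301 and the highest of the other splits 0, each being matched by 1 split, the real one. For week 14 the real count was 5388 and the highest other 3350, in a split that grouped week 14 replicate 1 with week 6 replicates 1 and 2. Across ages 3 of 100 splits of the 15 libraries, the real one included, gave at least the real 4471, the highest other being 6821. That share is under 0.05, but 100 splits fix it only roughly, so chance is made less likely and not excluded. These splits ignore cages, which mice of different ages shared. With cage as a factor edgeR called 0 genes across ages (1971 unadjusted), in a fit that was not run on simulated data. That count cannot tell a cage effect from lost power. Deviations from group means were no more alike in cage mates of different ages. Their median r was 0.00765 over 14 pairs, against 0.00643 over 76 Il10KO pairs from different cages. A part played by cage was thus not seen and is not excluded.

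Week 14 replicates 2 and 3, with low RIN, lay far from week 6, and replicate 1 near it. Degradation as the whole cause was made less likely by a likeness to week 10, where RINs were 8.5 to 9.0. The changes of replicates 2 and 3 from wild type followed those of week 10 from Il10KO week 6. Pearson's r across genes was 0.825 for the week 10 mean and 0.848, 0.81 and 0.566 for its replicates 1, 2 and 3. Part of this r may come from a shared trend with transcript length, and r was not computed without that trend. Spearman's rho between length and change was -0.36 for week 10 against week 6. For the low RIN libraries against week 10 it was -0.526. A swap of replicate 1 with a week 6 library would leave the true week 14 mouse under a week 6 label. Each week 6 library correlated with the mean of the other 2 at 0.9879 or more. Week 14 replicates 2 and 3 correlated with the week 6 mean at 0.764 and 0.795. A swap with a mouse that far from week 6 is thus argued against. A mildly changed mouse would not be seen, since wild-type replicate 2 had 0.987 and week 8 replicate 1 had 0.985. With replicate 1 as the only week 14 library, assumed to vary like the other groups, edgeR called 0 genes against week 6 (239 unadjusted) and 9 of 14 lists kept their call in camera. A single wrong label, degradation as part of the difference, weak or absent colitis, and a biopsy from a less affected part may each remain and were not told apart; its lipocalin label was 2044 ng/g.

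Matrix, endothelium and enteric neuron lists were lower at week 12 than at week 6 in camera with the preset correlation, but did not pass with an estimated one. Dilution by leukocyte RNA would lower all resident genes alike, but the tight junction list had a median of 0.087, and 16 of its 16 genes lay above the endothelium median of -1.76. After removal of the length trend its median was -0.214. Lists of epithelial cell types had medians of -0.32 (colonocyte), -0.50 (goblet), -0.32 (enteroendocrine), -0.21 (tuft) and -0.82 (crypt base). All lay above the endothelium median, so dilution is argued against as the whole cause and may remain in part. The smooth muscle list fell too, with a median of -0.94, but in each week 12 library it lay at least 0.624 above the endothelium list and 1.06 above the matrix list, which argues against less muscle wall as the whole cause for these. For the enteric neuron list, with a median of -1.07, less muscle wall may remain, since the smooth muscle list lay as little as -0.0122 above it. After removal of the length trend the medians lay further apart, at -1.65 for enteric neuron and -0.891 for smooth muscle. That comparison was not made in each library. Transcript length as the whole cause is argued against by the endothelium median after removal of the length trend, -1.54. A change in these cells with age or colitis may remain, as may a difference in biopsy depth that spares muscle, both untested, or in attached fat, whose list had a median of -1.48 (adjusted p = 0.164).

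At 6 weeks, lists differed between the genotypes in camera with the preset correlation, but none passed with an estimated one. The lower type I interferon list may come from 1 wild-type library: replicate 2 had a median of 3.24, the other wild-type libraries at most 0.661, within the Il10KO range of -0.73 to 0.90, though camera without replicate 2 still gave an adjusted p of 0.00102. For proliferation this is argued against, since the highest wild-type median was -0.735 and the lowest Il10KO median -0.33. Cage and genotype cannot be told apart, as 0 cages held both genotypes; genotype itself remains open.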

How the results depend on the processing

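Voom with a weight per group, the fit without the 3 week 14 libraries, and list tests without week 10 replicate 1 or week 14 replicate 1 were chosen only after the result was seen. Counts are of genes called. Where a count changed, the cause was not tested.

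DESeq2 called 25 genes for the genotype, 228, 5939 and 2507 for weeks 8, 10 and 12 against week 6, 881, 820 and 310 for consecutive ages, and 8217 across ages. RIN as a covariate gave 1, 193, 7584, 5751 and 0 (genotype, then weeks 8 to 14), and 1931, 1030 and 0 for consecutive ages. RIN differed widely only within week 14, so its counts of 0 there lean on replicate 1. Cage as a factor gave 0 for weeks 8, 12 and 14, 2 for week 10, 0 for the consecutive ages and 0 across ages. It could not be fitted for the genotype. The cage fit was not run on simulated data, so its power is not known. Only the compared groups gave 65, 0, 6177, 9186 and 0, and 0, 3 and 0. In data simulated with the same spread in every group this fit recovered 0% to 14% of genes changed 4-fold. Real spread differed by group, and for week 12 the simulation recovered 0% where the real fit called 9186 genes. The power behind its counts of 0 is thus not known, and they are not read as absence of change. Library size alone gave 17, 2310, 199 and 1937 for weeks 8 to 14, 16, 20 and 0, and 1451 across ages; the median of all genes then moved by -0.26, -0.15 and -0.56 for weeks 10, 12 and 14 and by -0.24, 0.11 and -0.27 for consecutive ages. Limma on TPM with a pseudocount of 1 gave 34, 664 and 9778 for weeks 8, 12 and 14, 20 for weeks 8 to 10 and 0 for weeks 12 to 14, with the median of all genes at -0.34, -0.36 and -0.74 for weeks 10, 12 and 14 against week 6, -0.29 for weeks 8 to 10 and -0.37 for weeks 12 to 14. With 0.1 it gave 35, 2021, 137 and 10067, and 2, 17 and 0, with medians of -0.52, -0.52, -1.15, -0.45 and -0.61 for the same 5 comparisons; 811 were higher and 1210 lower at week 10, 909 and 9158 at week 14, and 3 and 14 from week 10 to 12. Wild type as the reference gave 78 for week 8 and 612 for week 12. A filter of 1 CPM gave 67 and 110 for weeks 8 to 10 and 10 to 12. The replicate number as a block gave 3 for week 8, 14, 40 and 2 for consecutive ages and 1 for the lipocalin slope; the numbers do not pair the mice (median r 0.0159). RLE gave 0 and the length offset 2 for weeks 12 to 14. Without the 2 libraries of low RIN, week 14 gave 0 against week 6 and 0 against week 12, and the ages together 6988, with 1 library left at week 14 that is assumed to vary like the other groups; with the 15 Il10KO libraries alone they gave 2133. Voom with group weights gave 354, 166, 7023, 10096 and 1377, and 73, 191 and 0. Without the week 14 libraries the counts were 1, 134, 8354 and 6688, and 3493 and 1096.

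Leaving out each library in turn gave 0 to 0 genes for the genotype, 0 to 164, 767 to 5242, 0 to 52 and 1880 to 11335 for weeks 8 to 14, 0 to 24, 0 to 70 and 0 to 7707 for consecutive ages, 1261 to 11683 across ages and 0 to 2 for the slope. Lipocalin's rho with age was 0.954 to 0.97, its r with Lcn2 0.591 to 0.76, and 0.554 to 0.804 within age. For named genes with a call, 473 of 885 values kept it and 412 lost it; for those without, 195 stayed so, 9 gained a call and 3 changed sign. Under the other alternatives 1605 of 2030 values kept a call and 425 lost it; without a call, 298 stayed so, 57 gained one and 4 changed sign. Lcn2 between genotypes was -0.01 without wild-type replicate 2, -0.52 without Il10KO replicate 1 and at most 0.54, without Il10KO replicate 2. Rsad2 was 0.060 without wild-type replicate 2 and as low as -3.04, without wild-type replicate 1. From week 12 to 14, S100a8 was at -3.18 and -5.65 and Lcn2 at -1.26 and -1.96 with RIN as a covariate and without low RIN, and the neutrophil list turned lower (adjusted p = 0.0031 and 0.000709), the latter with 1 library at week 14.

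With an estimated correlation 0 lists passed in each comparison except 1 from week 10 to 12. From week 12 to 14, 16 lists passed with RIN as a covariate and 19 without low RIN, against 9. Without week 10 replicate 1, 21, 17 and 13 lists passed (week 10 against 6 and 8, and week 12 against 10), and without week 14 replicate 1, 16 and 7 (week 14 against 6 and 12). Further calls ended with cage as a factor for the neutrophil (0.0526) and endothelium (0.145) lists at week 8 and the regenerative list at week 10 (0.0699), and with wild type as the reference for the colonocyte list at week 14 (0.0919). Library size alone ended the colonocyte and smooth muscle calls at week 14 (0.0882 each), and RIN as a covariate the inflammatory cytokine (0.111), colonocyte (0.116) and smooth muscle (0.74) calls there. Except for the week 6 libraries in the genotype comparison, other list tests without single libraries were not run, and splits were not counted for lists. Limits of depth apply to Il10 and to genes without a count at week 6.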

Other observations

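The lists in this part were set before the data were examined, but choosing to describe them came only after the result was seen, as did the rank trend with transcript length and the relation of Lcn2 with age.

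The inflammatory monocyte list had 10 of 12 genes higher and 1 lower at week 10 against week 6 (adjusted p = 3.67e-05, and 0.409 with an estimated correlation). The crypt base list had medians of -1.14, -0.82 and -1.05 at weeks 10, 12 and 14 against week 6 (0.00319, 0.00946 and 0.00238, and 0.498, 0.667 and 0.686 with an estimated correlation). At week 14 the crypt base list had 0.286 with RIN as a covariate and 0.573 without the 2 libraries of low RIN, where 1 library is left.

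Spearman's rho across 16056 genes, which are not independent replicates, between transcript length and log2 change was -0.447 for week 12 and -0.36 for week 10 against week 6, and -0.526 for the low RIN libraries against week 10. Lcn2 rose with age with a rho of 0.6 over 15 mice (permutation p = 0.0209). Of 122 genes within 10 Mb of Il10, 3 had an unadjusted p under 0.05 between genotypes (2.46%, against 2.42% of all genes).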
